A study of Mus musculus with 6 samples.

How the data were processed

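RNA was measured in 6 mouse libraries labelled chondrocytes, 3 controls and 3 stimulated. Per the labels' protocols, libraries were made with a stranded poly(A) kit from pooled RNA of 3 donors with an integrity score above 9.0 and sequenced as paired reads of 101 bp, with a stated mean depth of 69000000 reads. Per the labels' protocols, reads were aligned to mm10 with TopHat and Bowtie, scaled by trimmed means and annotated with Cufflinks and Cuffdiff, and the submitters' processing notes also name GRCm38; versions are not given in the sources used here. The deposited files list every reference and assembled transcript of a library with its FPKM, a 95% interval and a coverage, so the FPKM are the authors' values per transcript; whether they include the trimmed-mean scaling is not given in the sources used here.

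Assembled gene identifiers differ between the deposited files, so transcripts were joined by RefSeq accession. Of 34026 accessions, 33669 matched a symbol in a RefSeq table of assembly GRCm38.p6, 281 were named by the files alone and 76 had no symbol. An assembled transcript was given to the gene that covered at least 50% of its exon bases on the same strand (bedtools 2.31.1), or otherwise to the single gene of its assembled locus. A gene's value was the sum of its transcripts' FPKM, for 24345 symbols. Assembled transcripts given to no gene held 3.72% to 6.30% of the FPKM of a library and were set aside. Coordinates are those of the files.

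A read scale was estimated from the files. The ratio of coverage to FPKM gives 692270 to 768640 reads per library, and coverage times transcript length over 101 bp sums to 743070 to 820560 reads. These estimated reads are not counts, and the scale of the coverage need not be the sequencing depth. In control replicate 1 the intervals of 100% of transcripts checked were centred on the FPKM within 1%, against 57.6% to 59.3% in the other 5 files, and the cause was not tested. If that file was processed differently, it is a batch of 1 library of 1 group, so the comparison was also run without it.

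The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, two-sided, for genes with a mean FPKM of at least 1, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Differences are on that scale, which understates the change of low genes. Tables were handled with Python 3.11.15 and pandas 2.3.3. On simulated libraries of 10110 genes the fit recovered 39% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold. These were drawn among genes of at least 5 FPKM. There were 15 false calls among 9891 unchanged genes. Those false calls were 10.1% of all calls, above the nominal 5%. The fixed list of cell cycle genes was also raised 2-fold, and it was called. The simulation assumed a spread between libraries (a dispersion of 0.02) and a fixed FPKM per read for each gene. It held no noise from assigning reads to isoforms, so these shares need not hold for the real libraries.

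Fixed gene lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. The 32 lists were cartilage matrix, hypertrophy, matrix proteases, protease inhibitors, cytokines with chemokines and NF-kB targets, interferon response, complement and acute phase, TGF-beta signalling, BMP signalling, Wnt signalling, integrins, toll-like receptor signalling, the Flightless and gelsolin family, fibroblast and fibrous matrix, sulfated glycosaminoglycan synthesis, cell cycle, hypoxia and glycolysis, unfolded protein response, oxidative stress and NRF2 targets, cholesterol synthesis, senescence and p53 targets, immediate early genes, ribosomal proteins, mitochondrially encoded genes, and markers of macrophages, osteoclasts, endothelium, osteoblasts, skeletal muscle, adipocytes, neural and Schwann cells, and other blood cells. Of these, 23 could be tested.

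The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took Flii, the 10 largest rises and falls among called genes whose groups did not overlap (without predicted genes, pseudogenes, small RNA genes and mitochondrial genes), the 3 members with the smallest adjusted p of each called list, 2 of each other list with a called member, the 2 most abundant members of each marker list of another cell type, and a fixed set of cartilage and inflammation genes. It gave 7 falls.

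Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median ratio scaling, quantile normalization, rescaling to a common sum, no intensity trend, array weights, a replicate block, a 2-fold minimum, the highest transcript of a gene, and the removal of each library. Reference transcripts alone, estimated reads scaled to a common sum (a mean of at least 2) and voom weights on estimated reads were added after seeing the data, as were 7 gene lists described under other observations.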

Results

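RNA sequencing of poly(A) RNA was examined in 6 libraries that the labels describe as primary mouse knee chondrocytes, the cells that make cartilage matrix. In 3 control libraries the cells had been cultured alone, and in 3 stimulated libraries they had shared medium for 48 h, across a porous insert, with macrophages activated by fragments of cartilage. Each library pooled RNA of 3 donors, and the labels do not say whether the pools of a group share donors, so p-values measure the spread between these pools. The deposited values were FPKM per transcript, and the coverage listed beside them corresponds to 768640, 749460 and 735440 reads in control replicates 1 to 3 and to 746630, 715590 and 692270 in stimulated replicates 1 to 3. The labels give a mean sequencing depth of 69000000 reads, and the reason for the gap is not given in the sources used here. The scale of the coverage need not be the sequencing depth, so the estimated reads given for some genes hold only if it is.

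Macrophage markers were abundant in all 6 libraries and held at most 8.68% of the estimated reads of a library. Ftl1 and Fth1, ferritin genes that most cells express, ranked 2 and 3 by mean FPKM. Lyz2, the macrophage lysozyme, stood at 52681 ± 4878 FPKM in controls and 53835 ± 4117 FPKM after stimulation (SD, n = 3 each), and reads of its near-identical copy Lyz1 cannot be told apart with certainty. Tyrobp, an adaptor of myeloid receptors, stood at 3881 ± 283 and 3987 ± 152 FPKM (SD, n = 3 each). The median of 25 macrophage markers lay between 384 and 557 FPKM in every library. The cartilage matrix list had a median of 0 FPKM in every library, and 18 to 20 of its 25 members were listed at 0. Col2a1, the main cartilage collagen, was listed at 0.550, 1.13 and 1.15 FPKM in controls and at 0.568, 0 and 1.22 FPKM after stimulation. Acan, which encodes aggrecan, was listed at 0.364 FPKM in control replicate 1 and at 0 in the other 5 libraries. Sox9, the chondrocyte transcription factor, did not exceed 0.367 FPKM in any library, and Col10a1, the collagen of hypertrophic chondrocytes, was listed at 0 in all 6. Some genes used by most cells, such as the squalene synthase gene Fdft1, were also listed at 0, so a 0 here is not evidence of absence. Because these levels go against the labelled cell type, the samples are called libraries labelled chondrocytes.

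**Figure D1:**
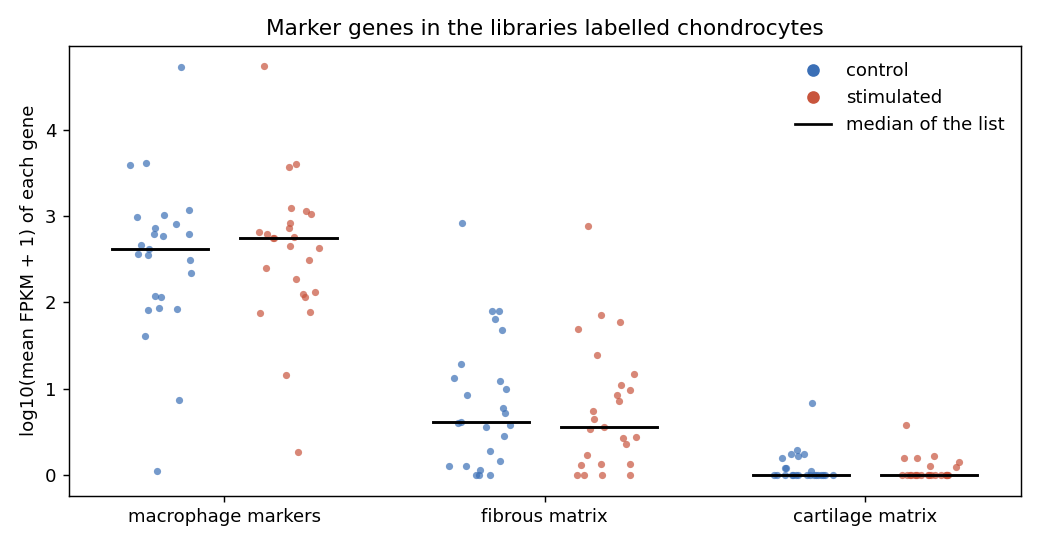
Mean FPKM of each member of 3 marker lists, on a log10 scale after adding 1, in control (blue) and stimulated (red) libraries, with n = 3 per group. Each point is a gene and each black line is the median of its list; in both groups the median macrophage marker lies above the median fibrous matrix gene, although single genes of these lists overlap, and most cartilage matrix genes lie at or near 0.

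Flii, the gene in the study's title, encodes Flightless I, an actin-binding protein of the gelsolin family. It lies on the minus strand of chromosome 11 from 60714146 to 60727263 (mm10) and has 2 RefSeq transcripts. Flii stood at 72.5 ± 4.60 FPKM in controls and 80.1 ± 10.6 FPKM after stimulation (SD, n = 3 each), from 195 to 274 estimated reads per library. The log2 difference was 0.14 with a standard error of 0.13 and a 95% interval from -0.16 to 0.43, which corresponds to 0.894-fold to 1.35-fold. It did not pass the test (limma adjusted p = 0.782), and a two-sided exact permutation test of the FPKM values gave p = 0.3, where 0.1 is the smallest p that 3 against 3 libraries allow. Gsn, the gelsolin gene, stood at 205 ± 13.8 and 204 ± 10.8 FPKM (SD, n = 3 each). None of the 6 tested members of the Flightless and gelsolin family list passed limma's test, over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05. The list was not called (camera in limma, adjusted p = 0.801), and its median of 0.07 and mean of 0.01 lay opposite to the direction of the test.

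Stimulated libraries held more transcript of acute phase and inflammatory genes. Marco, a scavenger receptor, rose from 25.8 ± 7.08 to 391 ± 35.8 FPKM (SD, n = 3 each), a log2 difference of 3.91 with a standard error of 0.20 (limma adjusted p = 0.000303). Saa3, an acute phase protein, rose 8.40-fold from 412 ± 55.7 to 3462 ± 461 FPKM (SD, n = 3 each; limma adjusted p = 0.000124). Cfb, complement factor B, rose from 2.26 ± 0.754 to 34.7 ± 7.58 FPKM (SD, n = 3 each; limma adjusted p = 0.00131). Fpr2, a formyl peptide receptor, rose 7.60-fold, Acod1, which makes itaconate, rose 7.28-fold, and Hp, which encodes haptoglobin, rose 6.42-fold. Ptges, the inducible prostaglandin E synthase, rose from 1.68 ± 0.256 to 16.9 ± 2.21 FPKM (SD, n = 3 each; limma adjusted p = 0.00195). Cfb rested on 3.25 to 6.48 estimated reads per control library and 51.9 to 87.6 per stimulated library. Ptges rested on 4.23 to 5.30 and on 37.1 to 49.9. The rule for named genes also took 3 genes whose values are uncertain or rest on few estimated reads in both groups. Ugt1a6b was listed at 0 in all controls and at 26.9 to 52.5 FPKM after stimulation, but it shares exons with the other Ugt1a genes. The 8 Ugt1a genes, Ugt1a6b among them, summed to 135 ± 11.5 FPKM in controls and 134 ± 9.66 FPKM after stimulation (SD, n = 3 each). The family total thus did not rise with Ugt1a6b, so the value of Ugt1a6b is uncertain. Nudt7 rested on at most 10.8 estimated reads in any library, and Etaa1os, an antisense-named transcript listed at 0 in all controls, on at most 3.23.

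Genes of antigen presentation by MHC class II were among those that fell. Cd74, the invariant chain, fell from 373 ± 38.5 to 197 ± 15.4 FPKM (SD, n = 3 each), a log2 difference of -0.91 with a standard error of 0.10 (limma adjusted p = 0.0141). H2-Eb1 fell from 76.7 ± 7.36 to 41.6 ± 0.926 FPKM (limma adjusted p = 0.0328) and H2-Ab1 from 169 ± 6.87 to 107 ± 6.81 FPKM (limma adjusted p = 0.0362; SD, n = 3 each). Postn, the matrix protein periostin, fell from 47.5 ± 1.59 to 23.9 ± 3.70 FPKM (SD, n = 3 each; limma adjusted p = 0.0451). Slco4a1, an organic anion transporter, fell from 27.0 ± 11.2 to 5.49 ± 0.354 FPKM, and Lgals3, which encodes galectin 3, from 2322 ± 46.7 to 1808 ± 53.6 FPKM (SD, n = 3 each). Ddx5, an RNA helicase, fell by 0.59 on the log2 scale in FPKM and by 0.26 when estimated reads were used.

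Of 10379 genes tested, 35 were higher and 8 were lower in stimulated libraries at an adjusted p below 0.05 (limma-trend on log2(FPKM + 1), two-sided, n = 3 per group), and in all 43 the groups did not overlap. Among all tested genes, 938 lay higher and 714 lower with no overlap, where chance gives 10% of genes in both directions together. The counts were smaller whenever 1 library was left out, where fewer libraries were fitted, and all 43 kept their direction each time. Without control replicate 1, the only file whose confidence intervals were all centred on the FPKM, the counts were 18 and 2. They were 26 and 3 without control replicate 2, 16 and 2 without control replicate 3, 11 and 0 without stimulated replicate 1, 14 and 2 without stimulated replicate 2, and 23 and 6 without stimulated replicate 3. With reads estimated from the deposited coverage in place of FPKM, a setting chosen after seeing the data, 138 genes were higher and 70 lower. Among them were all 41 of the 43 that could be tested there. Of the 19 alternatives other than the 2-fold minimum, Marco, Saa3, Ptges, Acod1, Il1b and Ugt1a6b were called in all 19, Cfb and Hp in 18 each, Fpr2 in 17, Cd74 and Nudt7 in 13 each, Adgre1 in 11, and Mmp14 and Ccl5 in 10 each. H2-Eb1, H2-Ab1 and Lgals3 were called in 9 each, Irak3 and Slco4a1 in 8 each, and Postn and Ddx5 in 7 each. Prdx1 was called in 6, Cd14 in 4, and Etaa1os in 6 of the 16 in which it was tested. All alternatives used the deposited assignment of reads to transcripts, so the 19 calls do not make the value of Ugt1a6b less uncertain.

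**Figure D2:**
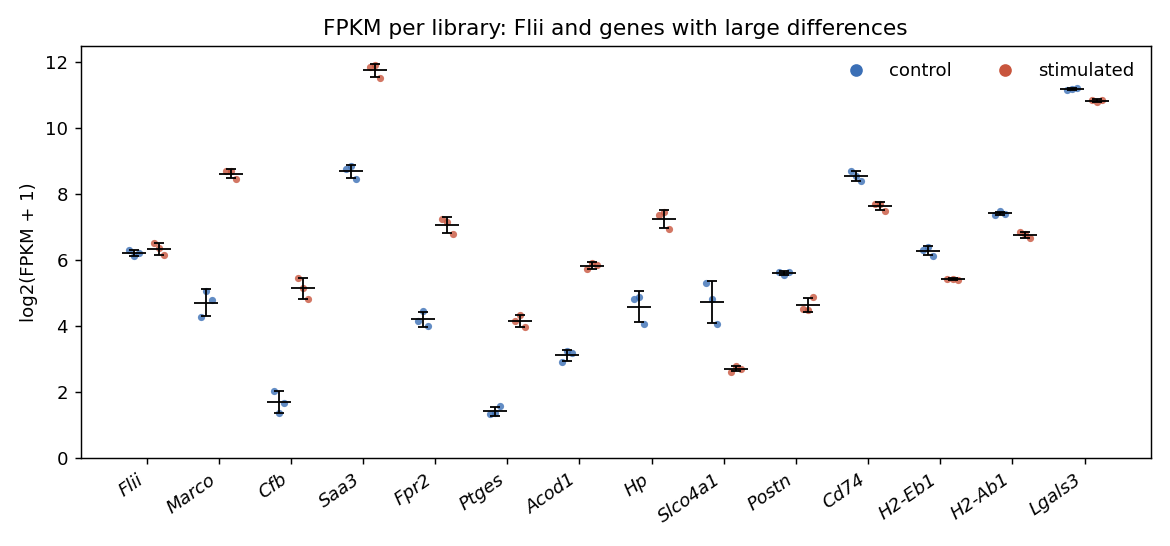
FPKM of Flii and of genes with large differences, as log2(FPKM + 1), in control (blue) and stimulated (red) libraries. Points are libraries (n = 3 per group) and black marks are the mean with its SD on the log2 scale; the groups of Flii overlap, with 72.5 and 80.1 FPKM as means, and those of the other genes do not.

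The list of cytokines, chemokines and NF-kB targets rose as a set. Of 26 tested members, 21 had a positive log2 difference, with a median of 0.61, and the list was called by camera (limma, adjusted p = 1.01e-10; adjusted p = 0.0487 with an estimated correlation). Ptges, Il1b and Ccl5 passed the test over all genes, and 14 members were higher and 1 lower when adjusted over the list alone. Il1b, the interleukin 1 beta gene, rose 6.30-fold from 2.38 ± 0.0534 FPKM (SD, n = 3 each; limma adjusted p = 0.003), with about 2 estimated reads per control library and about 14 per stimulated library. Ccl5, a chemokine, rose from 9.59 ± 2.50 to 40.2 ± 11.7 FPKM (SD, n = 3 each; limma adjusted p = 0.0334), with at most 18.3 estimated reads in any library. Il6 and Nos2 were listed at 0 in all 6 libraries, and Ptgs2, the inducible cyclooxygenase, stood at 4.84 ± 0.394 and 3.66 ± 0.527 FPKM (SD, n = 3 each; limma adjusted p = 0.697).

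Complement and acute phase genes rose as a set as well. Of 9 tested members 7 had a positive difference, with a median log2 difference of 0.98, and Saa3, Cfb, Hp and C3 passed the test over all genes, against 7 members adjusted over the list alone (camera in limma, adjusted p = 2.05e-10; adjusted p = 0.0487 with an estimated correlation). Of the toll-like receptor list, Irak3, an inhibitor of the pathway, rose from 26.0 ± 3.56 to 54.1 ± 5.10 FPKM (SD, n = 3 each; limma adjusted p = 0.0405), and Cd14, the co-receptor for lipopolysaccharide, from 118 ± 5.28 to 183 ± 14.8 FPKM (SD, n = 3 each; limma adjusted p = 0.047). Tlr7 stood at 64.8 ± 6.15 and 42.0 ± 5.14 FPKM and Tlr4 at 28.7 ± 1.69 and 21.3 ± 4.42 FPKM (SD, n = 3 each), and neither passed. That list was called upward with 5 members higher and 1 lower adjusted over the list alone (camera in limma, adjusted p = 0.0345), a call lost with an estimated correlation (adjusted p = 0.281 with an estimated correlation).

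Macrophage markers, which were abundant in both groups, were higher after stimulation by a small amount. Of 24 tested members 19 had a positive difference, with a median log2 difference of 0.14 (camera in limma, adjusted p = 2.22e-05; adjusted p = 0.0487 with an estimated correlation). Adgre1, which encodes the macrophage surface protein F4/80, rose from 365 ± 13.4 to 549 ± 22.0 FPKM (SD, n = 3 each; limma adjusted p = 0.0141), and Cd14 was the other member past the test over all genes, against 9 higher and 2 lower adjusted over the list alone. Aif1 stood at 39.7 ± 8.56 and 76.7 ± 14.2 FPKM (SD, n = 3 each; limma adjusted p = 0.134). Of the 25 macrophage markers, 2 (Cd14 and Ctss) also stood in another of the fixed lists.

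Sets of metabolic genes were also higher. In the hypoxia and glycolysis list 19 of 23 tested members had a positive difference, with a median log2 difference of 0.21 (camera in limma, adjusted p = 6.82e-05; adjusted p = 0.0487 with an estimated correlation). By limma none passed over all genes, 9 had an unadjusted p below 0.05 and 6 were higher adjusted over the list alone. Pfkl stood at 34.7 ± 4.52 and 58.6 ± 3.44 FPKM, and Gapdh at 934 ± 87.1 and 1201 ± 27.1 FPKM (SD, n = 3 each). In the cholesterol synthesis list 17 of 19 tested members had a positive difference, with a median of 0.37 (camera in limma, adjusted p = 8.75e-05; adjusted p = 0.0487 with an estimated correlation). By limma none of these passed alone by either adjustment and 5 had an unadjusted p below 0.05, as for Nsdhl, at 3.75 ± 0.783 and 7.65 ± 1.54 FPKM, and Msmo1, at 28.2 ± 4.17 and 44.0 ± 10.7 FPKM (SD, n = 3 each). The list of oxidative stress and NRF2 targets was called upward (camera in limma, adjusted p = 0.00841; adjusted p = 0.103 with an estimated correlation) with 13 of 20 tested members positive and a median log2 difference of 0.09. Prdx1, a peroxiredoxin, passed over all genes, from 2779 ± 60.1 to 3343 ± 7.07 FPKM (SD, n = 3 each; limma adjusted p = 0.0305), and 4 members were higher adjusted over the list alone.

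In the interferon response list 26 of 28 tested members had a positive difference, with a median log2 difference of 0.34 (camera in limma, adjusted p = 0.000105; adjusted p = 0.0666 with an estimated correlation). By limma no member passed over all genes, 5 had an unadjusted p below 0.05 and 1 was higher adjusted over the list alone. Bst2 stood at 85.6 ± 3.88 and 129 ± 17.7 FPKM, and Oasl2 at 10.1 ± 0.838 and 16.6 ± 3.02 FPKM (SD, n = 3 each). The ribosomal protein list was called upward with a median log2 difference of 0.05 and 26 of 35 tested members positive, none of them past limma's test by either adjustment and 5 at an unadjusted p below 0.05 (camera in limma, adjusted p = 0.0213; adjusted p = 0.536 with an estimated correlation). Over the macrophage markers the same comparison had a median log2 difference of 0.14.

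Fibroblast and fibrous matrix genes fell as a set, with 14 of 17 tested members negative and a median log2 difference of -0.38 (camera in limma, adjusted p = 0.000176; adjusted p = 0.134 with an estimated correlation). Postn passed over all genes and 4 members were lower adjusted over the list alone. Col1a1, the main fibrous collagen, stood at 79.0 ± 7.28 and 47.8 ± 3.77 FPKM (SD, n = 3 each; limma adjusted p = 0.0804), and Col6a1 at 12.3 ± 1.15 and 6.19 ± 1.28 FPKM (SD, n = 3 each; limma adjusted p = 0.154). The protease inhibitor list was called downward with 7 of 9 tested members negative and a median log2 difference of -0.22, although by limma none passed by either adjustment and 2 had an unadjusted p below 0.05 (camera in limma, adjusted p = 0.0197; adjusted p = 0.491 with an estimated correlation). Its Timp2 stood at 138 ± 5.70 and 120 ± 2.55 FPKM, and its Serpinb2 at 13.3 ± 0.503 and 9.70 ± 0.179 FPKM (SD, n = 3 each). While these lists were lower, the macrophage markers were higher by a median of 0.14 on the log2 scale. Of the 11 lists called by camera at the preset correlation, 5 were called with an estimated correlation and 8 by fry.

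**Figure D3:**
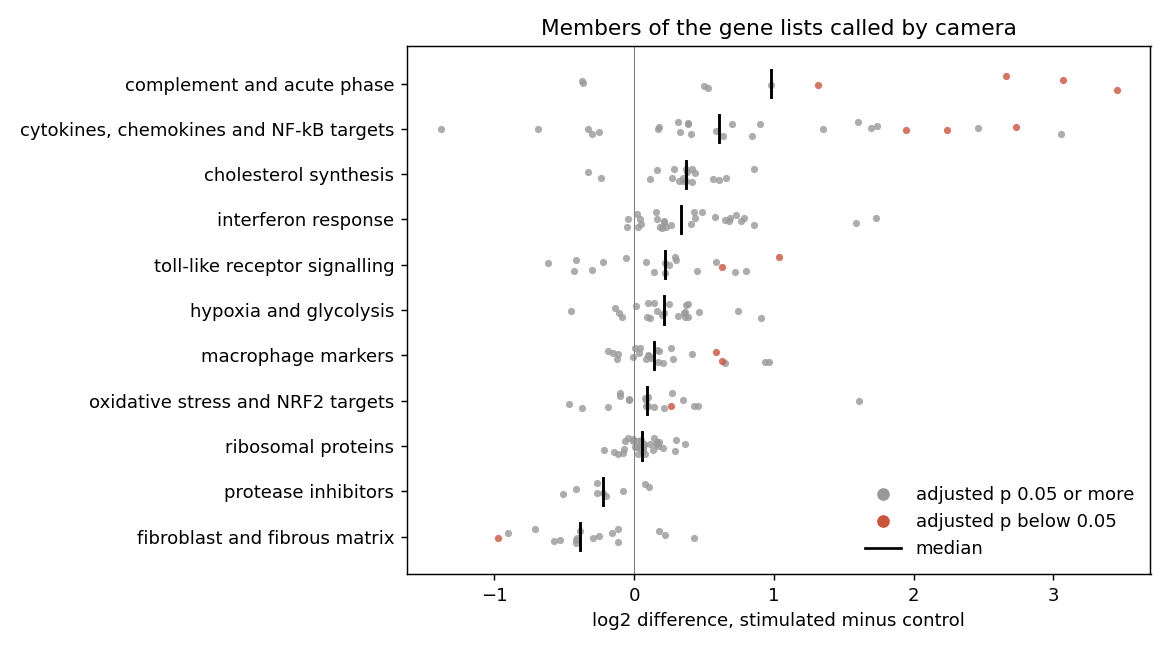
Log2 difference of stimulated minus control libraries for each tested member of the 11 lists called by camera at a preset correlation. Each point is a gene, red where its own adjusted p was below 0.05, and black bars are list medians, from -0.38 for fibrous matrix genes to 0.98 for complement and acute phase genes.

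The matrix protease and hypertrophy lists were not called. In the matrix protease list Mmp14, a membrane-bound matrix metalloproteinase, rose from 67.3 ± 7.08 to 141 ± 21.4 FPKM (SD, n = 3 each; limma adjusted p = 0.0328), and its log2 difference was -1.71 when reference transcripts alone were counted. Mmp12 stood at 626 ± 48.1 and 481 ± 20.1 FPKM and Mmp13 at 11.9 ± 1.75 and 8.83 ± 0.842 FPKM (SD, n = 3 each), and neither passed. Mmp3 was listed at 0 in all 6 libraries, Adamts4 reached at most 1.12 FPKM and Adamts5 at most 0.494 FPKM. The list had 2 members higher and 3 lower adjusted over the list alone, and its median log2 difference of -0.09 and mean of 0.04 differed in sign (camera in limma, adjusted p = 0.286). In the hypertrophy list none of 9 tested members passed limma's test by either adjustment and 2 had an unadjusted p below 0.05 (camera in limma, adjusted p = 0.769), and Runx2 stood at 2.22 ± 0.836 and 2.03 ± 0.475 FPKM (SD, n = 3 each).

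The other tested lists were not called either, by camera in limma. The adjusted p was 0.751 for TGF-beta signalling, 0.457 for BMP signalling, 0.769 for integrins, 0.918 for sulfated glycosaminoglycan synthesis and 0.599 for the cell cycle. It was 0.798 for the unfolded protein response, 0.439 for senescence and p53 targets, 0.993 for immediate early genes and 0.5 for osteoclast markers. No member of these 9 lists passed limma's test over all genes, and 0 to 6 members per list had an unadjusted p below 0.05. Adjusted over the list alone, 1 member was higher for TGF-beta signalling, 1 lower for BMP signalling, 1 higher for glycosaminoglycan synthesis, and 2 higher and 1 lower for osteoclast markers. The median and mean differed in sign for integrins (-0.01 and 0.04), for glycosaminoglycan synthesis (-0.06 and 0.06) and for the unfolded protein response (0.04 and -0.00052). Fewer than 5 members could be tested for the cartilage matrix list (1 of 25), Wnt signalling (3 of 25), and the endothelial (1 of 13), osteoblast (2 of 12), skeletal muscle (2 of 17), adipocyte (3 of 10), neural and Schwann (3 of 10) and other blood cell (4 of 17) markers. The highest values among these came from genes that macrophages can also express: Lpl at 302 ± 34.6 and 328 ± 15.5 FPKM in the adipocyte list and S100a9 at 443 ± 22.4 and 391 ± 96.5 FPKM in the blood cell list (SD, n = 3 each). Vwf stood at 7.68 ± 0.616 and 7.17 ± 0.298 FPKM (SD, n = 3 each). The 13 mitochondrially encoded genes had no reference transcript in the tables used here.

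At the level of single reference transcripts, 21 of 12689 tested were higher and 16 lower (limma-trend, adjusted p below 0.05, n = 3 per group). Of these 37, 26 were listed at 0 in every library of 1 group, and 1 of the 24 genes they belong to was itself called. Whether their FPKM moved to other transcripts of the gene was not tested over the set, but values of Naxd, Pmvk and Ly6i went that way. Naxd and Pmvk each had a called transcript listed at 0 in all controls and another listed at 0 in all stimulated libraries. For Pmvk these averaged 11.7 FPKM after stimulation and 10.8 FPKM in controls. A called Ly6i transcript fell from a mean of 13.8 to 0 FPKM, while the sum of the gene rose from 13.8 to 44.6 FPKM. The assignment of reads to isoforms varied within groups too: the Flii transcript NM_001302207 was listed at 39.3, 0 and 37.2 FPKM in the 3 controls and at 0 in the stimulated libraries. Without control replicate 1 the count of changed transcripts was above 37. It was 22 or 17 without control replicate 2 or 3, and 1, 24 or 10 without stimulated replicate 1, 2 or 3.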

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

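The tests in this part were chosen after the results were seen, and those of scaling, isoform assembly and macrophage share replaced a first form that had already been run. No value met the rules for a closer look: groups of 3 are too small for a test of single libraries, and none of 311 assembled loci given to no gene passed limma (smallest adjusted p = 0.528, 12 at an unadjusted p below 0.05).

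Macrophage transcripts, with Lyz2 at 52681 and 53835 FPKM in controls and stimulated libraries, were abundant in all 6 libraries labelled chondrocytes. If that came only from macrophages carried over from the co-culture, the controls, cultured alone, would hold far less of them, but the median log2 difference of the markers was 0.14. Cultured chondrocytes that had lost their cartilage phenotype would carry fibrous matrix transcripts above macrophage transcripts, but the median fibrous matrix gene reached at most 0.0101 of the median macrophage marker in any library. RNA mainly from macrophages in every library stays open as a candidate explanation: the median macrophage marker was at least 99.0 times the median fibrous matrix gene, but that value restates the pattern and is no separate support. Whether the samples were exchanged or the cultures were overgrown stays open.

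The 43 genes called between the groups were the second pattern. Unequal scaling would shift all genes alike, but the median log2 difference of all tested genes was at most 0.031 in size as deposited or rescaled to a common sum, against at least 0.27 for a called gene; 40 of the 43 were still called under median ratio scaling and 34 under quantile normalization. Differences in isoform assembly stay open. With estimated reads all 41 that could be tested were still called, but 12 were with the highest transcript and 13 with reference transcripts only. Those last settings leave out FPKM given to other transcripts of a gene, so a call can also be lost through that choice. A higher share of the same macrophages is argued against for the 3 to 20 genes called higher in 4 libraries, whose median in the held-out pair lay at least 1.72 above the upper quartile of the markers over the 9 pairs, but it stays open for smaller rises, as do macrophages of another state from the co-culture and the stimulation itself. The 10 splits of 6 libraries are too few for a share under 0.05; the real split called 43 genes, 1 of the 10 splits did so, and the highest other split called 3.

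Fibrous matrix genes were lower in stimulated libraries, and a smaller share of stromal cells would lower them alike. Over all 12 members with a mean of at least 20 estimated reads over the 6 libraries this is argued against: the intervals of 5 left out their weighted mean, with Fn1 and Tnc on the other side of 0. Without Fn1, S100a4 and Tnc, which other cells can also express and which were left out after their values were seen, 1 of 9 intervals (Postn) did so, and the explanation stays open for those 9 because a lower share and lower expression in the same cells cannot be told apart at this spread. The verdict therefore rests on that choice of members. The first form of the check, a chi-square approximation of heterogeneity that was replaced because it does not suit so few libraries, had given 1.31e-09 over all members and 0.0126 without those 3.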

How the results depend on the processing

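Reference transcripts only, estimated reads scaled to a common sum and voom on estimated reads were chosen after seeing the data; the other alternatives were planned. The Flii difference kept its direction and stayed short of the threshold under all alternatives run, from 0.04 to 0.81, the latter with the highest transcript. Against 35 genes higher and 8 lower, there were 18 and 4 with no intensity trend, 18 and 15 with the highest transcript, 138 and 70 with estimated reads, and 150 and 83 with voom on estimated reads. Of the 43 genes called, 12 were still called with the highest transcript and 13 with reference transcripts only, and 41 kept their direction in each. There were 15 higher and 6 lower with reference transcripts only. At a minimum of 2-fold, 2 genes were lower. Leaving out 1 library gave 11 to 26 higher and 0 to 6 lower genes, and 1 to 40 isoforms against 37. Fewer libraries were fitted there, and for the other changes in counts the cause was not tested. Of 11 lists called, 7 were called with the highest transcript and 5 with an estimated correlation. The same replicate number does not mark a shared donor or day in the labels. Deviations of libraries with the same number correlated at -0.01, 0.02 and 0.03, within the range of -0.065 to 0.045 for libraries with different numbers. The values thus gave no sign of pairing by number, but noise in single libraries could hide a weak one. With a replicate block there were 13 genes higher, 1 lower, 10 lists and 1 isoform.

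Of 1242 values for the 66 named genes tested, 1044 kept direction and side of the threshold, 154 kept direction only and lost the call, 22 gained a call and 22 reversed. With the highest transcript the log2 difference was -1.71 for Mmp14, -0.21 for Aldoa, -0.0081 for Lyz2, -0.30 for Pmp22, -2.75 for Rpl27, 0.58 for Runx2 and 0.18 for Gsn, and with reference transcripts only it was -1.71 for Mmp14, -0.0081 for Lyz2 and -2.75 for Rpl27. For Lyz2 it was -0.0049 when rescaled to a common sum. Leaving out 1 library gave -0.030 to 0.10 for Lyz2, -0.013 to 0.092 for Tyrobp, -0.92 to 0.41 for Mylpf, -0.30 to 0.081 for Runx2 and -0.056 to 0.042 for Gsn. The ribosomal list reversed with quantile normalization (camera in limma, adjusted p = 0.676). Of the 21 alternatives run for the lists, its call was kept in 8, lost in 12 and reversed in 1. That of the toll-like receptor list was kept in 11 and lost in 10. Each other called list kept its call in at least 17. The cause of these changes and reversals was not tested. If the coverage gives the depth, the libraries held 692270 to 768640 reads. The simulation drew on the other estimate, coverage times transcript length over 101 bp. That estimate sums to 743070 to 820560 reads, including transcripts given to no gene, which the simulation left out. In the simulated libraries 39% of genes changed 2-fold and 94% of genes changed 4-fold were recovered, all of them genes of at least 5 FPKM. A 2-fold change was thus often missed there. The simulation used an assumed dispersion of 0.02 and no noise from assigning reads to isoforms, so the shares need not hold for the real libraries.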

Other observations

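The lists, members and tests in this part were chosen after the values were seen, so they describe these libraries and are not independent evidence. All 8 tested members of an MHC class II list had a negative log2 difference, with a median of -0.61; 3 passed the test over all genes and 4 had an unadjusted p below 0.05, while H2-DMa and H2-DMb1 differed by -0.06 each and H2-DMb2 by -0.22, all within their standard errors (camera in limma over 7 added lists, adjusted p = 1.05e-06; adjusted p = 0.0389 with an estimated correlation). Of 31 lysosomal genes, 24 had a negative difference with a median of -0.05 (camera adjusted p = 0.000241, or adjusted p = 0.0511 with an estimated correlation). By limma on FPKM none passed alone and 9 had an unadjusted p below 0.05. With estimated reads Creg1, Atp6v0d2, Lgmn, Ctss, Man2b1, Ctsd, Pld3 and Psap passed limma's test as lower, Creg1 with a log2 difference of -0.28. Only Ctsz passed as higher, with 0.32. Of 17 genes of lipid efflux and storage, 10 had a negative difference with a median of -0.18 (camera adjusted p = 0.000603, or adjusted p = 0.0556 with an estimated correlation). On FPKM none was past limma's test and 7 were at an unadjusted p below 0.05. With estimated reads Gpnmb, Apoe, Fabp5, Plin2 and Abcg1 passed limma's test, all of them lower. Actin cytoskeleton genes were called upward with a median of 0.14 (adjusted p = 0.000116 with camera; adjusted p = 0.0556 with an estimated correlation), with Actg1 and Tagln2 past the test over all genes.

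Scavenger and lectin receptors were called upward (adjusted p = 0.00922 with camera; adjusted p = 0.0609 with an estimated correlation), but the median log2 difference was 0.04 and Marco and Clec4e were the 2 members past the test over all genes. Monocyte markers were called upward with a median of 0.29 (adjusted p = 0.0136 with camera; adjusted p = 0.254 with an estimated correlation), with 7 of 11 tested members positive and 4 negative. Ly6c2, a gene that shares sequence with Ly6c1, passed the test over all genes, while Ccr2, a chemokine receptor of classical monocytes, had a log2 difference of -0.72 and did not. Genes of alternative macrophage activation were not called (adjusted p = 0.42 with camera).

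Xist was listed at 19.8 to 23.6 FPKM in the 6 libraries, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 6.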
